A study of Mus musculus with 8 samples.

How the data were processed

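RNA was extracted with TRIzol from the livers of Glul flox/flox and GlulΔlyz2 mice that had received H2O, or LPS (1 mg/kg) together with D-GalN (200 mg/kg). Per the labels, libraries were made with the NEBNext Ultra kit and sequenced on an Illumina NovaSeq instrument. The time between injection and collection is not given in the sources used here.

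The authors deposited 1 table of FPKM (fragments per kilobase of gene, scaled to the fragments assigned to genes in each library) with 55416 genes and 1 column per library, and its columns were matched to the 8 samples by the sample descriptions. The submitters' processing notes list DESeq2 3.15 and the genome build GRCm39. The aligner, the counting tool and the annotation are not given in the sources used here. The unit was checked on the values: multiplied by the summed exon length of GENCODE M21 (52083 genes matched by identifier), between 98.2% and 98.5% of the values above 0 in each library lay within 0.01 of a whole number of fragments, and the step gave the total of assigned fragments per library. That total ran from 18381670 to 24799143, so that 1 fragment in a gene of 1 kb is worth between 0.0403 and 0.0544 FPKM. Of the 55416 genes 1492 had no symbol and 1705 shared one. Genes without a symbol were kept under their Ensembl identifiers. Where identifiers shared a symbol, the identifier with the highest mean FPKM kept the symbol alone. The others were kept under the symbol joined to their Ensembl identifier.

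Values were used as log2(FPKM + 1), with the scaling between libraries as deposited. The added 1 FPKM shrinks the change of genes near or under that level. Genes with at least 1 FPKM in at least 2 libraries (13708) were tested with limma 3.58.1 in R 4.3.3, using a model with 1 mean for each of the 4 groups, 4 residual degrees of freedom, and empirical Bayes moderation with a trend in the variance. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 13708 genes in each comparison, with a threshold of 0.05. A gene is said to have risen, fallen or changed only where it passed. The 6 comparisons were injury against H2O averaged over both genotypes, the same within floxed and within KO mice, KO against floxed under injury and under H2O, and the interaction. A further 36 lists of genes for liver cell types, metabolism, inflammation, stress and cell death were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry of limma served as alternatives. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

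The lists, the tests of the 6 comparisons and the rule for naming genes were fixed before the data were examined. That rule allows Glul and Lyz2, the 8 largest rises and the 8 largest falls in each comparison among genes that passed and whose groups do not overlap, up to 4 members with the smallest p in each list described, and a panel of Tnf, Il1b, Il6, Ccl2, Cxcl1, Saa1, Alb, Cps1, Cyp7a1, Cyp2e1, S100a8, Clec4f, Ccr2, Cdkn1a and Hif1a in every comparison.

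The model was tested on simulated data with 200 changed genes and a dispersion of 0.021. It recovered between 56% and 99% of 2-fold and between 96% and 100% of 4-fold changes in the 5 comparisons of groups, and 11% and 92% for the interaction. In the same order as above, 16 of 215, 10 of 175, 17 of 180, 12 of 165, 19 of 175 and 22 of 125 calls were false.

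Settings tried beside these, chosen in advance, were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median centring, quantile normalisation, array weights, robust variance estimation, a model of only the groups compared, the replicate number as a block, and leaving out each library in turn. The replicate number is that of the sample titles, which do not say that libraries with the same number share a batch. With 1 library left in a group, that library is assumed to vary like the other groups. Chosen after the values were seen were voom on the fragments recovered from the FPKM values, a scaling that leaves out mitochondrial and haemoglobin genes, and a filter of at least 5 FPKM in 2 libraries.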

Results

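Livers of mice in 4 groups were profiled by bulk RNA sequencing, with 2 libraries per group and 8 in all. Floxed control mice (Glul flox/flox) were compared with GlulΔlyz2 mice (KO), which lose Glul, the gene for glutamine synthetase, in cells that express Cre recombinase from the Lyz2 locus, mainly macrophages, monocytes and neutrophils. Each genotype had received H2O or 1 mg/kg lipopolysaccharide (LPS) with 200 mg/kg D-galactosamine (D-GalN) by intraperitoneal injection. LPS activates macrophages, and D-GalN blocks RNA synthesis in hepatocytes and so makes them sensitive to tumour necrosis factor. The title of the study concerns whether loss of glutamine synthetase in myeloid cells worsens this injury by way of monocyte-derived macrophages. The labels do not say whether the 2 libraries of a group came from separate animals, so each p-value measures only the spread between these libraries.

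The number of assigned fragments per library that the FPKM values imply was 21261348 and 23432978 in H2O-treated floxed livers, 19516450 and 23578664 in injured floxed livers, 21331305 and 18381670 in H2O-treated KO livers, and 24799143 and 21295002 in injured KO livers. At this depth 1 fragment in a gene of 1 kb corresponds to between 0.0403 and 0.0544 FPKM. Of 55416 genes, 13708 reached 1 FPKM in at least 2 libraries and were tested. The first principal component, with 66.8% of the variance, placed the H2O libraries between -69.9 and -58.5 and the injured ones between 47.9 and 75.9. On the second component, with 24.2%, injured KO livers stood at 58.7 and 36.2 and injured floxed livers at -61.3 and -55. The 4 H2O libraries lay between 1.8 and 7.5. Haemoglobin genes took 2.00% and 0.285% of the fragments in injured KO livers, 0.00446% and 0.00442% in injured floxed livers, and between 0.0108% and 0.0228% in the H2O libraries. Mitochondrial genes took 6.99% and 6.94% in injured floxed livers, 10.4% and 12.6% in injured KO livers, and between 12.5% and 22.6% in the H2O libraries.

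**Figure D1:**
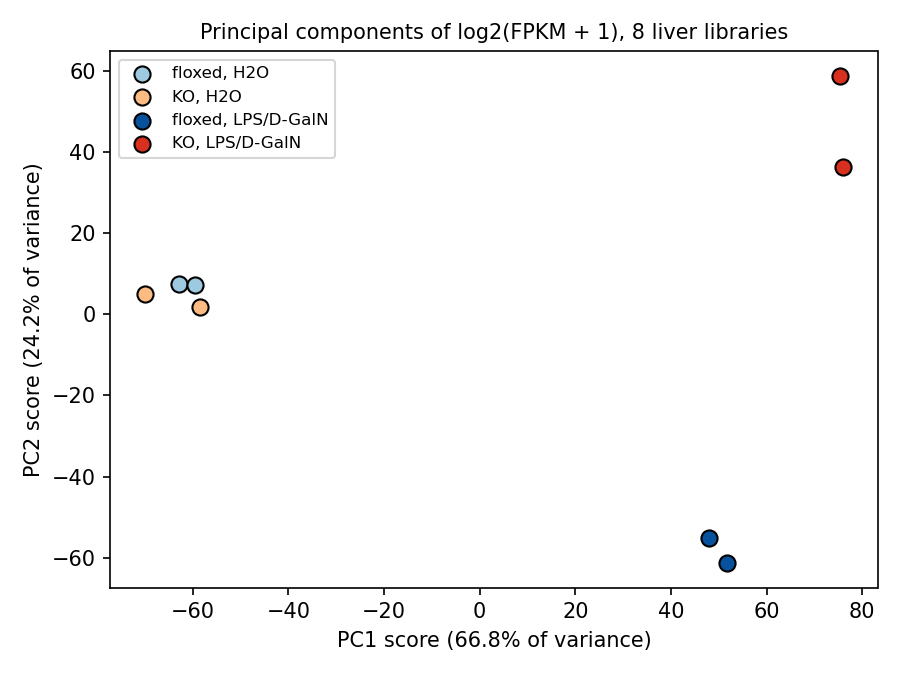
Scores of the 8 libraries on the first and second principal components of log2(FPKM + 1) over 13708 genes, 1 point per library, coloured by group. Injured libraries lie to the right of the H2O libraries, and the second component parts injured KO (58.7 and 36.2) from injured floxed livers (-61.3 and -55).

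Glul (ENSMUSG00000026473) was followed first, because its loss defines the KO mice; in the liver, hepatocytes around the central vein express most of it. Its level in H2O-treated livers was 106 ± 1.17 FPKM in floxed and 112 ± 31.5 FPKM in KO mice (SD, n = 2 each). Injury raised it to 297 ± 85.9 FPKM in floxed livers, a log2 change of 1.44 ± 0.27 (SE), whereas injured KO livers had 82.3 ± 11 FPKM, a log2 change of -0.42 ± 0.27. The adjusted p of these changes was 0.00304 in floxed and 0.214 in KO livers, and their difference, the genotype by injury interaction, was -1.86 ± 0.39 with an adjusted p of 0.0096. Glul was lower in injured KO than in injured floxed livers, with a log2 difference of -1.82 ± 0.27 (adjusted p = 0.00135). Averaged over both genotypes Glul rose by 0.51 ± 0.19 (adjusted p = 0.0442), a call that leaving out any of 6 libraries ended. The adjusted p of Glul was 0.0943 and 0.0997 without H2O-treated floxed replicate 1 and 2, 0.151 without injured floxed replicate 1, 0.123 without H2O-treated KO replicate 1, and 0.058 and 0.12 without injured KO replicate 1 and 2, with log2 changes between 0.36 and 0.58. The call also ended with the replicate block (0.0623), with no filter (0.106), after quantile normalisation (0.0592) and with the scaling that leaves out mitochondrial and haemoglobin genes (0.0649). Lyz2 (ENSMUSG00000069516), lysozyme 2 of macrophages and neutrophils and the locus that carries Cre, had 53.1 ± 27.3 FPKM in H2O-treated floxed livers and 7.60 ± 3.29 in H2O-treated KO livers. It had 20.2 ± 6.06 FPKM in injured floxed and 36.3 ± 5.14 in injured KO livers. The log2 change of Lyz2 under injury was -1.28 ± 0.40 in floxed livers (adjusted p = 0.0276) and 2.16 ± 0.40 in KO livers (adjusted p = 0.00236), with an interaction of 3.45 ± 0.57 (adjusted p = 0.00452). The fall in floxed livers did not pass without H2O-treated floxed replicate 2 (-0.74, adjusted p = 0.161) or injured floxed replicate 1 (-0.99, 0.161), nor after median centring (0.0651) or with no filter (0.105). Lyz2 did not pass in the other comparisons, at -2.61 ± 0.40 under H2O (adjusted p = 0.16), 0.84 ± 0.40 under injury (0.118) and 0.44 ± 0.29 for injury averaged over both genotypes (0.201). The last of these passed at 0.71 without H2O-treated floxed replicate 2 (adjusted p = 0.0419), and the difference in Lyz2 under H2O passed with voom (-2.79, adjusted p = 0.0232) and among genes with a mean of at least 5 FPKM (-2.61, 0.0377) or at least 5 FPKM in 2 libraries (-2.61, 0.0463).

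**Figure D2:**
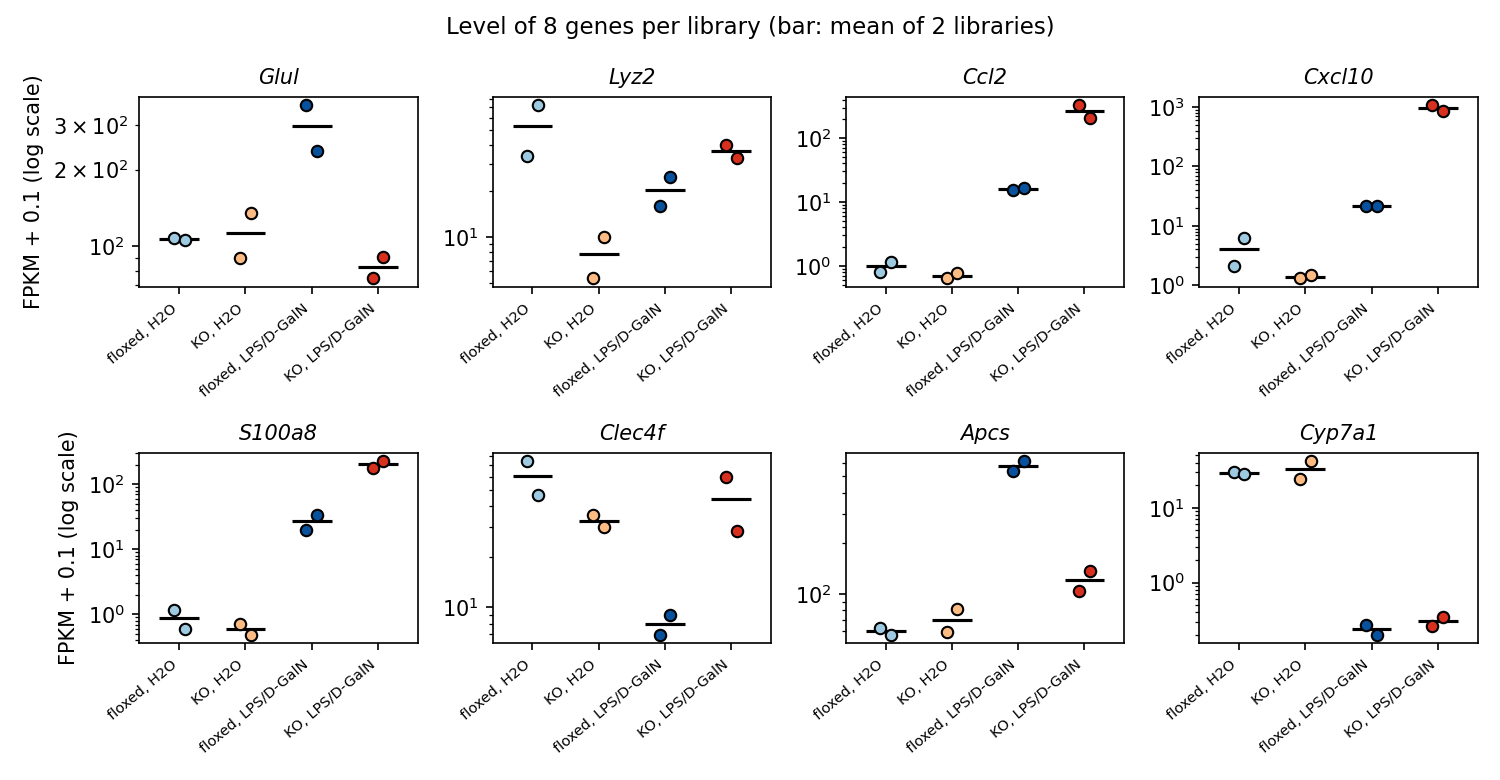
Level of 8 genes in each library, in FPKM on a log axis with 0.1 added, 1 point per library and a bar at the mean of the 2 libraries of each group. Glul is at 297 FPKM in injured floxed and 82.3 FPKM in injured KO livers, and Ccl2 at 15.9 and 268 FPKM.

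What LPS/D-GalN did to the liver was asked over both genotypes together. Injury raised acute-phase, inflammatory, interferon-response and immediate early genes and lowered genes of bile acid and lipid synthesis. Lcn2 (ENSMUSG00000026822), an iron-sequestering protein of the acute phase, went from 1.80 ± 0.389 to 2189 ± 2.71 FPKM in floxed and from 1.24 ± 0.00794 to 1044 ± 506 FPKM in KO livers (SD, n = 2 each), a log2 change of 9.20 ± 0.22. Values in parentheses after a gene are log2 changes of FPKM + 1 with their SE. Of 27 tested acute-phase genes 24 rose and 0 fell (24 and 1 adjusted over the list alone), among them the metallothionein Mt1 (8.58 ± 0.15) and the serum amyloid genes Saa3 (7.98 ± 0.14) and Saa1 (7.66 ± 0.23), the last with a close paralog of near-identical sequence in Saa2 (8.67 ± 0.29). Of 23 cytokine and chemokine genes 22 rose and 0 fell, with the same counts adjusted over the list alone, as for every list below for which no second count is given. They include the neutrophil attractant Cxcl1 (5.86 ± 0.18), the monocyte attractant Ccl2 (5.27 ± 0.16), Tnf (2.91 ± 0.12), Il1b (3.81 ± 0.35) and Il6 (1.86 ± 0.16). Among NF-kB target genes 19 of 20 rose, such as the adhesion molecule Icam1 (3.80 ± 0.15) and the feedback inhibitor Tnfaip3 (4.43 ± 0.22). Interferon-response genes rose in 22 of 23 cases, such as the guanylate-binding protein gene Gbp2 (6.75 ± 0.16). All 16 neutrophil genes rose, with S100a8, a calprotectin subunit, at 5.50 ± 0.20, as did 14 of 15 monocyte and macrophage genes. Of 14 genes of inflammatory (M1) macrophages, 13 rose and 1, Irf5, fell. The adjusted p with an estimated correlation was 0.15 for the acute-phase list and 0.158 for each of the other 6 lists just named, against at most 4.02e-08 with the preset correlation. Of 9 genes of M2 macrophages 5 rose and 3 fell. Their list was not called (camera adjusted p = 0.0774, and 0.413 with an estimated correlation).

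All 16 immediate early genes rose in the same comparison, among them Ier3 (5.77 ± 0.23) and the transcription factor Atf3 (3.99 ± 0.12), and so did 15 of 17 genes of the unfolded protein and integrated stress response. Among p53 and apoptosis genes 14 of 17 rose, such as the cell cycle inhibitor Cdkn1a (4.49 ± 0.13), and 1, Bbc3, fell. With an estimated correlation the adjusted p was 0.15 for the immediate early and p53 lists and 0.164 for the stress list. Glycolysis and hypoxia genes rose in 13 of 18 cases and fell in 3, with Pfkfb3, which makes an activator of glycolysis, at 4.38 ± 0.12 and Hif1a at 2.42 ± 0.16 (adjusted p = 0.356 for the list with an estimated correlation). In the opposite direction 14 of 17 bile acid genes fell and 0 rose (15 and 0 adjusted over the list alone). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, went from 29.3 ± 1.19 to 0.137 ± 0.0497 FPKM in floxed and from 32.8 ± 12.3 to 0.206 ± 0.0589 FPKM in KO livers (-4.75 ± 0.16), and Cyp8b1, which makes cholic acid, fell as well (-3.95 ± 0.19). Of 18 lipid synthesis genes 14 fell and 0 rose, including Hmgcs1 of the cholesterol pathway (-3.24 ± 0.13) and fatty acid synthase Fasn (-2.77 ± 0.18). Both lists had an adjusted p of 0.158 with an estimated correlation. G6pc, glucose-6-phosphatase of gluconeogenesis (-6.36 ± 0.48), and Hjv, a regulator of hepcidin (-5.28 ± 0.24), fell as well. The Kupffer cell marker Clec4f fell (-1.22 ± 0.25, adjusted p = 0.00329). Cps1 of the urea cycle (-0.34 ± 0.21, adjusted p = 0.181) and Cyp2e1 of drug metabolism (0.33 ± 0.20, 0.179) did not pass, nor did albumin (Alb, -0.18 ± 0.18, 0.385), whose change was 0.48 (adjusted p = 0.0229) after quantile normalisation. Without H2O-treated KO replicate 1 Alb (-0.33, adjusted p = 0.0399) and Cps1 (-0.59, 0.00611) passed, as did Cyp2e1 without H2O-treated KO replicate 2 (0.51, 0.0353) and after median centring (0.58, 0.0431).

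Smaller lists also passed camera with the preset correlation. Of 7 T and NK cell genes 5 rose and 1 fell, of 8 cholangiocyte genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), of 16 stellate cell and fibroblast genes 5 rose and 3 fell (5 and 2), and of 8 red blood cell genes 6 rose. Pyroptosis and necroptosis genes rose in 7 of 13 cases and fell in 2, and genes of the glucocorticoid and fasting response rose in 9 of 13 cases and fell in 2. With an estimated correlation their adjusted p was 0.208, 0.413, 0.711, 0.51, 0.314 and 0.268 in that order. The stellate call (adjusted p = 0.0271) was lost after median centring (0.0552), without injured KO replicate 1 (0.0946) and without injured floxed replicate 1 (0.0525). Tested within each genotype, all 6 lists were called in KO livers, where with an estimated correlation their adjusted p was 0.126, 0.341, 0.523, 0.375, 0.227 and 0.341 in the order of the lists above. In floxed livers the glucocorticoid and fasting list alone was called (0.309 with an estimated correlation). The interaction passed for the T and NK cell, stellate, red blood cell and pyroptosis lists with the preset correlation (adjusted p = 4.28e-05, 0.000377, 0.000887 and 0.00169) and not with an estimated one (0.267, 0.478, 0.432 and 0.406). It did not pass for cholangiocytes (0.0513, and 0.462 with an estimated correlation). With the scaling that leaves out mitochondrial and haemoglobin genes it passed for them (0.0445). Red blood cell genes rose in 7 of 8 cases in KO livers (8 adjusted over the list alone; median 3.80), while in floxed livers 0 rose and 2 fell (0 and 0; median -0.82, adjusted p = 0.996). Stellate cell and fibroblast genes had 10 rises and 2 falls in KO livers, against 2 rises and 4 falls in floxed livers (adjusted p = 0.747). In floxed livers the adjusted p was 0.435 for T and NK cells, 0.264 for cholangiocytes and 0.093 for pyroptosis and necroptosis (0.0416 without injured floxed replicate 1).

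In all, 9481 of 13708 genes passed, 3301 higher and 6180 lower after injury. The median of all genes lay at -0.26 on the log2 scale in this comparison, so the direction of small changes depends on the scaling between libraries. After median centring 4664 genes were higher and 4549 lower, which is 50.6% higher against 34.8% with the values as deposited. Quantile normalisation gave 48.3% higher. Mitochondrial genes, which took a smaller share of the fragments in injured than in H2O-treated livers of both genotypes, fell in 12 of 13 cases (13 adjusted over the list alone), or in 6 after median centring. Within floxed livers 9 of the 13 fell, and within KO livers 2 (0 adjusted over the list alone). Over both genotypes the list did not pass (adjusted p = 0.0691, and 0.711 with an estimated correlation). It passed after median centring (0.032), with the replicate block (0.0415) and without H2O-treated KO replicate 1 (0.0478) or 2 (0.00396).

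Injury was then tested within each genotype. In floxed livers the acute-phase response was joined by falls in markers of resident cells. Of 27 acute-phase genes 25 rose (adjusted p = 0.142 with an estimated correlation), with Steap4, an inflammation-induced metalloreductase, going from 14.5 ± 0.569 to 2755 ± 649 FPKM (7.46 ± 0.27) and the protease inhibitor Serpina3n, which has close paralogs, from 46.9 ± 1.70 to 4884 ± 182 FPKM (6.67 ± 0.37). Cytokine genes rose in 17 of 23 cases and fell in 2, Il18 and Cxcl11, and neutrophil genes rose in 15 of 16. Of 13 Kupffer cell genes 10 fell and 0 rose (11 and 0 adjusted over the list alone), among them Clec4f (-2.77 ± 0.36), the apoptosis inhibitor of macrophages Cd5l (-2.77 ± 0.24) and the iron exporter Slc40a1 (-3.12 ± 0.13). B cell genes fell in 8 of 9 cases (9 adjusted over the list alone), such as the immunoglobulin light chain Igkc (-3.58 ± 0.40). With an estimated correlation the adjusted p was 0.309 for cytokines, 0.27 for neutrophils, 0.561 for Kupffer cells and 0.571 for B cells. The p53 list rose in 13 of 17 cases and fell in 2, with Cdkn1a (4.70 ± 0.19) and the p53 target Ccng1 (3.17 ± 0.15) among those that rose. Its adjusted p was 0.142 with an estimated correlation. G0s2, an inhibitor of lipolysis, fell (-5.46 ± 0.55), as did the water channel Aqp8 (-4.87 ± 0.22), Cyp7a1 (-4.74 ± 0.23) and G6pc (-6.91 ± 0.67). Saa1 (8.26 ± 0.32), Cxcl1 (6.08 ± 0.26), S100a8 (3.93 ± 0.28), Ccl2 (3.18 ± 0.22), Hif1a (2.36 ± 0.23), Il1b (2.18 ± 0.49) and Tnf (1.95 ± 0.16) rose. Il6 rose by 0.83 ± 0.22 (adjusted p = 0.0146), but did not pass without H2O-treated floxed replicate 2 (0.0657), injured floxed replicate 1 (0.0624) or injured floxed replicate 2 (0.0635), nor with no filter (0.0588). Alb (-0.28 ± 0.25, adjusted p = 0.363; 0.65 and 0.0331 after quantile normalisation), Cps1 (-0.04 ± 0.30, 0.908) and Cyp2e1 (0.60 ± 0.29, 0.11) did not pass. Cyp2e1 passed without H2O-treated KO replicate 1 (0.0496), after median centring (0.88, adjusted p = 0.0414), with array weights (0.0478) and in a model of only the groups compared (0.03).

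In KO livers chemokine and neutrophil genes were among the largest rises. The interferon-induced chemokine Cxcl10 went from 1.29 ± 0.120 to 960 ± 160 FPKM (8.70 ± 0.36), Ccl2 from 0.602 ± 0.0946 to 268 ± 83.8 FPKM (7.36 ± 0.22) and the calprotectin subunit S100a9 rose by 7.62 ± 0.31. Of 23 cytokine genes 22 rose and 0 fell, and all 20 NF-kB targets, all 15 monocyte and macrophage genes, all 16 neutrophil genes and all 16 immediate early genes rose. Each of these 5 lists had an adjusted p of 0.126 with an estimated correlation. Tnf (3.87 ± 0.16), Il1b (5.43 ± 0.49), Il6 (2.89 ± 0.22), S100a8 (7.07 ± 0.28), Cxcl1 (5.64 ± 0.26), Saa1 (7.07 ± 0.32), Cdkn1a (4.27 ± 0.19) and Hif1a (2.48 ± 0.23) rose. Kupffer cell genes rose in 7 of 13 cases and fell in 2, without a call for the list (adjusted p = 0.075; 0.0289 without injured KO replicate 2), with the scavenger receptor Marco at 5.26 ± 0.45 and Clec4f at 0.33 ± 0.36 (adjusted p = 0.445). Endothelial genes rose in 8 of 16 cases and fell in 3 (adjusted p = 0.0134), such as the adhesion molecule Cdh5 (3.54 ± 0.24). That call was lost without injured KO replicate 1 (adjusted p = 0.095) and with an estimated correlation (adjusted p = 0.626). Of 18 lipid synthesis genes 16 fell and 0 rose, with Hmgcs1 at -3.87 ± 0.19, and of 17 bile acid genes 14 fell and 0 rose (15 and 0 adjusted over the list alone), with Cyp7a1 at -4.76 ± 0.23 (adjusted p = 0.126 for both lists with an estimated correlation). G6pc fell (-5.81 ± 0.67). Alb (-0.08 ± 0.25, adjusted p = 0.796), Cps1 (-0.64 ± 0.30, 0.0957) and Cyp2e1 (0.06 ± 0.29, 0.859) did not pass. Cps1 passed without H2O-treated KO replicate 1 (-1.13, adjusted p = 0.00398), after quantile normalisation (-0.92, 0.0191) and with the scaling that leaves out mitochondrial and haemoglobin genes (-0.74, 0.0351).

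The number of genes past the threshold was 7861 in floxed livers, 2537 higher and 5324 lower, and 8639 in KO livers, 3062 higher and 5577 lower. With array weights it was 8822 in floxed and 7845 in KO livers. After median centring 49.7% of the changed genes were higher in floxed and 48.2% in KO livers, against 32.3% and 35.4% as deposited. Genes that rose in both genotypes numbered 1227, against 567 that independent calls would give, and 3592 fell in both, against 2166. Opposite calls were rarer than that: 266 genes rose in floxed and fell in KO livers, against 1032, and 339 the reverse, against 1189. Across the 13708 genes, which are not independent replicates, the changes in floxed and KO livers had a Pearson r of 0.65 and a Spearman rho of 0.59.

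**Figure D3:**
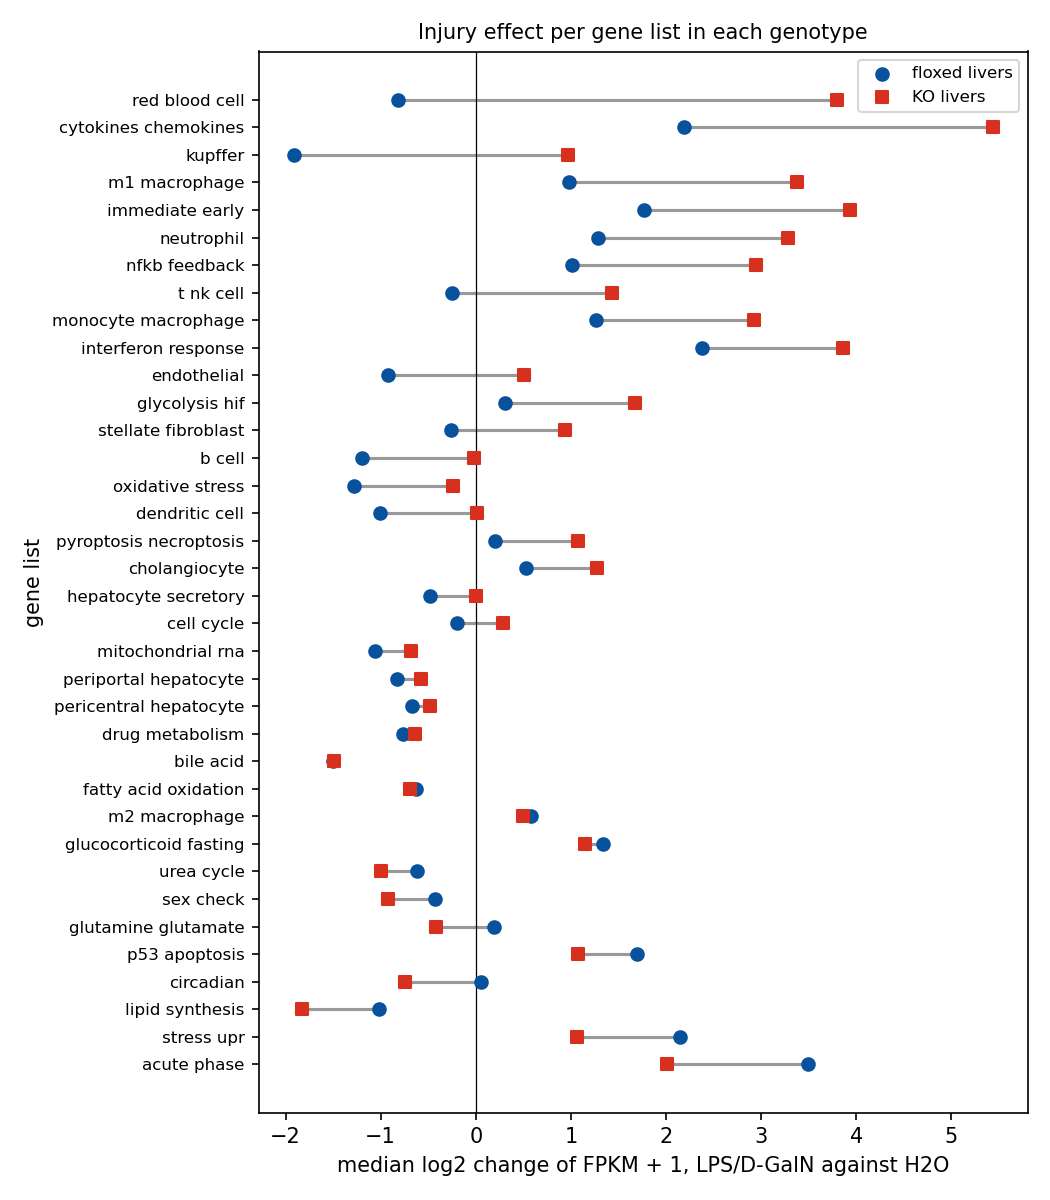
Median log2 change of FPKM + 1 over the tested members of each of the 36 gene lists after injury, with 1 circle for floxed and 1 square for KO livers joined by a line. The Kupffer cell list lies at -1.91 in floxed and 0.97 in KO livers, and the acute-phase list at 3.49 and 2.02.

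The comparison that bears on the study's question is that of injured KO with injured floxed livers. Injured KO livers had more cytokine, NF-kB, neutrophil, macrophage, lymphocyte and endothelial transcripts and fewer acute-phase and lipid synthesis transcripts. Cxcl10 stood at 960 ± 160 FPKM in KO and 21.3 ± 0.257 FPKM in floxed livers (SD, n = 2 each), a log2 difference of 5.42 ± 0.36. Ccl2, which draws monocytes by way of the receptor Ccr2, stood at 268 ± 83.8 and 15.9 ± 0.643 FPKM (3.95 ± 0.22); Ccr2 itself lay under the expression filter. Of 23 cytokine genes 21 were higher and 0 lower (22 and 0 adjusted over the list alone), including the granulocyte growth factor Csf3 (3.59 ± 0.14), Il1b (3.12 ± 0.49), Il6 (2.00 ± 0.22) and Tnf (1.64 ± 0.16). Cxcl1 did not differ past the threshold (-0.13 ± 0.26, adjusted p = 0.697). NF-kB targets were higher in 17 of 20 cases, such as the subunit genes Nfkb1 (2.13 ± 0.13) and Relb (2.32 ± 0.21). All 16 neutrophil genes were higher, including S100a8 (2.91 ± 0.28) and the decoy receptor Il1r2 (2.31 ± 0.15), and so were 14 of 15 monocyte and macrophage genes, including the matrix protein gene Thbs1 (3.57 ± 0.29) and the C-type lectin Clec4d (2.22 ± 0.18). All 14 genes of inflammatory macrophages were higher, with the nitric oxide synthase Nos2 at 2.72 ± 0.20. This list shares members such as Il1b, Tnf and Il6 with the cytokine list. Of 9 genes of M2 macrophages 6 were higher and 2 lower. Their list was not called (camera adjusted p = 0.0885, and 0.459 with an estimated correlation). Kupffer cell genes were higher in 10 of 13 cases (11 adjusted over the list alone), among them the complement gene C1qa (2.25 ± 0.34), at 66.6 ± 16.8 against 13.1 ± 2.98 FPKM, and Clec4f (2.26 ± 0.36). With an estimated correlation the adjusted p was 0.342 for cytokines, 0.388 for NF-kB targets, 0.303 for neutrophils and for inflammatory macrophages, 0.33 for monocytes and macrophages and 0.459 for Kupffer cells. The share of haemoglobin fragments in these libraries was 2.00% and 0.285% in KO against 0.00446% and 0.00442% in floxed livers, and all 8 red blood cell genes were higher, with Hbb-bs at 7.30 ± 0.72 (adjusted p = 0.459 for the list with an estimated correlation; Hbb-bs and Hbb-bt, like Hba-a1 and Hba-a2, have near-identical sequences).

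Markers of other cell types moved the same way between injured KO and injured floxed livers. All 7 T and NK cell genes were higher, such as granzyme B (Gzmb, 2.20 ± 0.19), as were 7 of 9 B cell genes and 5 of 7 dendritic cell genes. Higher too were 13 of 16 endothelial genes with Cdh5 at 2.72 ± 0.24 and 10 of 16 stellate cell and fibroblast genes (13 adjusted over the list alone) with the smooth muscle actin Acta2 at 1.83 ± 0.19. In these 5 lists 0 genes were lower. With an estimated correlation their adjusted p was 0.303, 0.459, 0.303, 0.459 and 0.546. Immediate early genes were higher in 15 of 16 cases, with Ier2 at 3.62 ± 0.20 and Gadd45b at 4.37 ± 0.28 (adjusted p = 0.303 for the list with an estimated correlation). Glycolysis and hypoxia genes were higher in 10 of 18 cases and lower in 1, Bnip3, with the lactate transporter Slc16a3 at 2.59 ± 0.17 (adjusted p = 0.459 with an estimated correlation), while Hif1a did not pass (-0.12 ± 0.23, adjusted p = 0.685). Hilpda, a hypoxia-inducible lipid droplet protein, stood at 98.2 ± 3.18 against 3.25 ± 0.132 FPKM (4.54 ± 0.16). Of 13 pyroptosis and necroptosis genes 7 were higher, among them Nlrp3 of the inflammasome (1.86 ± 0.26) and the necroptosis kinase Ripk3 (1.68 ± 0.20), with an adjusted p of 0.459 with an estimated correlation. In the opposite direction 17 of 27 acute-phase genes were lower and 2, Socs3 and Il1rn, higher (18 and 3 adjusted over the list alone). They include Apcs, the serum amyloid P component, at 120 ± 22.7 against 576 ± 52.1 FPKM (-2.26 ± 0.23), and Steap4 (-2.18 ± 0.27), and the list had an adjusted p of 0.459 with an estimated correlation. Lipid synthesis genes were lower in 11 of 18 cases and higher in 1, Srebf1, with squalene epoxidase Sqle at -2.64 ± 0.21 (adjusted p = 0.303 with an estimated correlation). The p53 target Ccng1 was lower (-3.01 ± 0.15), as were the citrate transporter Slc13a5 (-3.55 ± 0.30), the glycosyltransferase B3galt1 (-4.03 ± 0.24), the tight junction protein Cldn2 (-3.06 ± 0.20) and Syvn1, a ubiquitin ligase of the endoplasmic reticulum (-3.06 ± 0.39). Alb (0.02 ± 0.25, adjusted p = 0.968; -0.65 and 0.0347 after quantile normalisation), Cps1 (-0.52 ± 0.30, 0.181), Cyp7a1 (0.08 ± 0.23, 0.781) and Cyp2e1 (-0.48 ± 0.29, 0.203) did not pass. Cps1 passed without H2O-treated KO replicate 1 (0.0301) or 2 (0.0302), after quantile normalisation (-0.87, adjusted p = 0.0276) and in a model of only the groups compared (0.0455).

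In total 7192 genes differed between injured KO and injured floxed livers, 3464 higher and 3728 lower in KO, of which 1961 and 1261 differed at least 2-fold. After median centring 3794 were higher and 3417 lower. Injured KO replicate 1 listed 32782 genes above 0, against 27058 in its partner and 23005 and 23024 in the injured floxed libraries; without it 5635 genes passed. Saa1 was lower (-0.91 ± 0.32, adjusted p = 0.047), a call lost without injured KO replicate 1 (-0.56, 0.247), injured floxed replicate 1 (-1.04, 0.0997) or injured floxed replicate 2 (-0.78, 0.188). It was also lost with a pseudocount of 0.1 (0.055), with no filter (0.13), after median centring (0.0697) and with array weights (0.0509). The same held for a model of only the groups compared (0.0691), the replicate block (0.0545) and the scaling that leaves out mitochondrial and haemoglobin genes (0.0588). Cdkn1a was lower (-0.67 ± 0.19, adjusted p = 0.0183), a call lost when any 1 of the 4 injured libraries was left out (adjusted p = 0.0749 and 0.0737 without floxed replicate 1 and 2, 0.0638 and 0.0525 without KO replicate 1 and 2). The interferon-response list (10 of 23 higher, 1 lower, Ifit2; adjusted p = 0.0418, with Mx2 at 2.14 ± 0.16) lost its call after median centring (0.0514), with a pseudocount of 0.1 (0.0509), with an estimated correlation (adjusted p = 0.706), and without injured KO replicate 2 (0.234), injured floxed replicate 2 (0.0695) or H2O-treated KO replicate 1 (0.0529) or 2 (0.053). The mitochondrial list (6 of 13 higher, 0 lower; 5 adjusted over the list alone; adjusted p = 0.0126) lost it without injured KO replicate 2 (0.109) or injured floxed replicate 2 (0.0537) and with an estimated correlation (adjusted p = 0.643).

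**Figure D4:**
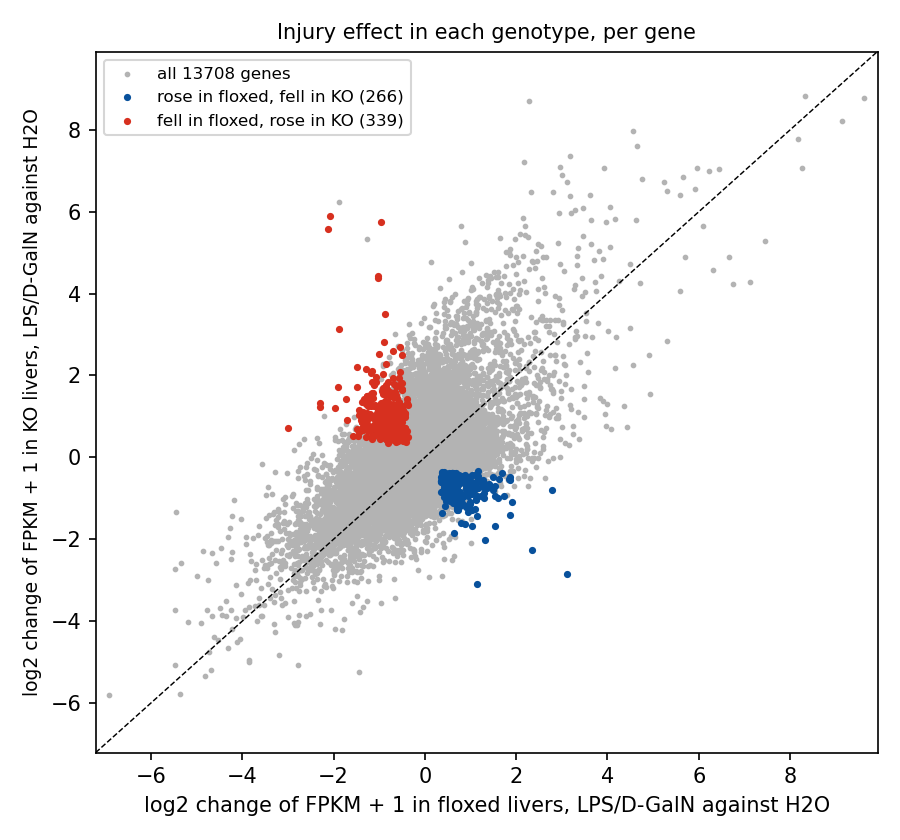
Log2 change of FPKM + 1 after injury in KO livers against that in floxed livers, 1 grey point per gene for 13708 genes, with the genes called in opposite directions coloured (266 rose in floxed and fell in KO livers, 339 the reverse). The dashed line marks equal changes in both genotypes.

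The genotypes were compared without injury as a baseline. Between H2O-treated KO and floxed livers 1 gene passed, Oas2 (ENSMUSG00000032690), an interferon-induced sensor of double-stranded RNA, at 4.06 ± 0.0342 FPKM in KO and 15.3 ± 0.495 FPKM in floxed livers (SD, n = 2 each; -1.69 ± 0.14, adjusted p = 0.0349). It passed in 0 of the 8 fits that leave out 1 library, where its adjusted p ran from 0.105 to 0.279. Nor did it pass in a model of only the groups compared (0.318) or with the replicate block (0.181). The unadjusted p was under 0.05 for 780 genes, and voom on the recovered fragments called 14 genes. Of 23 interferon-response genes 14 were lower in KO adjusted over the list alone, though 0 passed over all genes, with Oasl2 at -1.32 ± 0.17 (adjusted p = 0.114), Gbp3 at -1.16 ± 0.16 (0.123) and the transcription factor Irf7 at -1.84 ± 0.31 (0.187). Among genes with a mean of at least 5 FPKM, 17 passed, among them Oasl2 (0.035), Gbp3 (0.0377) and Irf7 (0.0486). Their adjusted p with voom was 0.0232, 0.0279 and 0.0232, and with at least 5 FPKM in 2 libraries Oasl2 (0.0439) and Gbp3 (0.0463) passed. Adjusted over the list alone 9 of 13 Kupffer cell genes were lower, among them C1qa (-1.37 ± 0.34, adjusted p over all genes 0.382) and Timd4, a receptor for dying cells (-1.06 ± 0.20, 0.26), and 7 of 15 monocyte and macrophage genes, among them Ms4a4c (-0.98 ± 0.14, 0.146; -2.03 and 0.0468 with a pseudocount of 0.1) and the Fc receptor gene Fcgr1 (-0.99 ± 0.15, 0.16). Camera with the preset correlation gave adjusted p = 2.22e-19, 1.61e-11 and 6.35e-07 for these 3 lists, and camera with an estimated correlation gave adjusted p = 0.462 for each. Glul (0.05 ± 0.27), Saa1 (0.28 ± 0.32), Cxcl1 (0.31 ± 0.26), Ccl2 (-0.22 ± 0.22), Tnf (-0.28 ± 0.16), Il1b (-0.13 ± 0.49), Il6 (-0.06 ± 0.22), S100a8 (-0.24 ± 0.28), Cdkn1a (-0.24 ± 0.19), Hif1a (-0.24 ± 0.23), Alb (-0.19 ± 0.25), Cps1 (0.08 ± 0.30), Cyp7a1 (0.11 ± 0.23) and Cyp2e1 (0.06 ± 0.29) had an adjusted p of 1, and Clec4f (-0.84 ± 0.36) of 0.876. In all 12 of 36 lists passed with the preset correlation, 0 with an estimated correlation and 0 with fry. The interferon, Kupffer cell and monocyte lists kept their call without each of the 8 libraries in turn. The other 9 lost it at least once, among them the mitochondrial list without H2O-treated KO replicate 1 (adjusted p = 0.399).

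Whether injury acted differently in the genotypes was tested as the interaction, the log2 change in KO minus that in floxed livers. A positive value means a larger rise, a smaller fall, or a rise in place of a fall in KO livers. Most interactions of inflammatory and macrophage genes were positive, while among acute-phase genes more were negative than positive. Cxcl10 (6.42 ± 0.50), Ccl2 (4.18 ± 0.31), S100a8 (3.14 ± 0.39), Il6 (2.06 ± 0.32), Tnf (1.92 ± 0.23) and Il1b (3.25 ± 0.70) had positive interactions, as did the matricellular gene Ccn1 (5.42 ± 0.52) and Gadd45b (5.03 ± 0.40). Il1b lost its call with no filter (adjusted p = 0.0554). Ifi27l2a, an interferon-induced gene, went from a mean of 27.0 to 6.42 FPKM in floxed and from 5.46 to 55.8 FPKM in KO livers (5.01 ± 0.38). Of 23 cytokine genes 22 had a positive interaction. So had all 16 neutrophil, all 15 monocyte and macrophage, all 14 inflammatory macrophage and 12 of 13 Kupffer cell genes. In these lists 0 genes had a negative one. Of the 13 Kupffer cell genes 10 fell and 0 rose in floxed livers, against 2 falls and 7 rises in KO livers. Kupffer cell genes include Clec4f (3.10 ± 0.51), C1qa (3.62 ± 0.48) and Timd4 (2.20 ± 0.28), whose mean levels under H2O were lower in KO than in floxed livers. With an estimated correlation the adjusted p was 0.334 for cytokines and Kupffer cells and 0.267 for the other 3 lists. Of 9 genes of M2 macrophages 5 had a positive and 1 a negative interaction (6 and 2 adjusted over the list alone). Their list was not called (camera adjusted p = 0.13, and 0.456 with an estimated correlation). Interferon-response genes had a positive interaction in 15 of 23 cases (adjusted p = 0.432 with an estimated correlation), such as Mx2 (2.70 ± 0.22). Endothelial genes had one in 11 of 16 cases (13 adjusted over the list alone, adjusted p = 0.434 with an estimated correlation), such as Cdh5 (3.30 ± 0.33). Of these 16 genes 11 fell and 1 rose in floxed livers, against 3 falls and 8 rises in KO livers. Of 27 acute-phase genes 12 had a negative and 2 a positive interaction (13 and 2 adjusted over the list alone), with Apcs at -2.46 ± 0.32 and Steap4 at -2.16 ± 0.39 (adjusted p = 0.406 for the list with an estimated correlation). B3galt1 (-4.60 ± 0.34), Cldn2 (-3.21 ± 0.29), Slc13a5 (-3.21 ± 0.43) and Ccng1 (-2.86 ± 0.21) also had negative interactions. Saa1 (-1.19 ± 0.46, adjusted p = 0.0776), Cxcl1 (-0.44 ± 0.36, 0.37; -0.83 and 0.0454 without injured KO replicate 1), Cdkn1a (-0.43 ± 0.26, 0.236), Hif1a (0.12 ± 0.32, 0.795), Alb (0.20 ± 0.36, 0.684), Cps1 (-0.60 ± 0.42, 0.304; -1.08 and 0.0232 without H2O-treated KO replicate 1), Cyp7a1 (-0.02 ± 0.33, 0.964) and Cyp2e1 (-0.54 ± 0.41, 0.337) did not pass. Quantile normalisation brought Saa1 (-1.42, adjusted p = 0.0489) and Cdkn1a (-0.96, 0.0297) past the threshold, as leaving out injured KO replicate 2 did for Saa1 (-1.54, 0.0421).

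The interaction passed for 4940 genes, 2871 of them positive and 2069 negative. In 1080 genes with a positive interaction a rise was called in KO livers with no call in floxed livers. In 711 a fall was called in floxed livers with no call in KO livers, and 339 fell in floxed and rose in KO livers. Among negative interactions 788 genes were called lower in KO livers with no call in floxed livers, 595 were called higher in floxed livers with no call in KO livers, and 266 rose in floxed and fell in KO livers. The count dropped to 2997 without injured floxed replicate 1 and to 3263 without H2O-treated floxed replicate 1. Quantile normalisation made 48.1% of the interactions positive, against 58.1% with the values as deposited.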

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

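Tests chosen only after the result was seen are that of the splits of the libraries and that of the share of hepatocyte RNA. The response to LPS/D-GalN differed between the genotypes in many genes. A test of that difference itself, the interaction in limma, called 4940 genes, and 266 genes rose in floxed and fell in KO livers while 339 fell in floxed and rose in KO livers. Both counts lay under the 1032 and 1189 genes that independent calls would give. Among the inflammatory genes the difference of the log2 changes (KO minus floxed) was 6.42 for Cxcl10, 4.18 for Ccl2, 3.25 for Il1b, 3.14 for S100a8, 2.06 for Il6 and 1.92 for Tnf. Il1b lost its call with no filter (adjusted p = 0.0554). It was 5.01 for Ifi27l2a and 2.70 for Mx2 of the interferon response, and 5.42 for Ccn1 and 5.03 for Gadd45b. In macrophage markers it was 3.45 for Lyz2, 3.62 for C1qa, 3.10 for Clec4f and 2.20 for Timd4, and in the endothelial gene Cdh5 it was 3.30. The clock repressor Nr1d1 stood at 2.83. The difference was negative for Glul (-1.86), Apcs (-2.46), Steap4 (-2.16), Ccng1 (-2.86), B3galt1 (-4.60), Cldn2 (-3.21) and Slc13a5 (-3.21). Without injured floxed replicate 1 the count of genes was 2997, and without H2O-treated floxed replicate 1 it was 3263.

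For injury against H2O in all 8 libraries, chance was examined by splitting the libraries in other ways. In a model of 2 groups the real split gave 6471 genes. Of the 35 splits into 4 and 4 libraries 1 gave as many (the real one), and the highest of the others gave 0. Each other split puts injured and H2O libraries on both sides, which widens the spread within its sides and favours low counts there. The lowest share this test can give is 1 of 35, and the labels do not state that the libraries are independent. It therefore does not exclude chance.

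Of marker lists for 9 cell types other than hepatocytes, 8 were called higher in injured KO than in injured floxed livers. The cholangiocyte list (4 of 8 genes higher) was not (adjusted p = 0.0547; 0.0477 and 0.0478 without H2O-treated floxed replicate 1 and 2, 0.013 without injured floxed replicate 1), and with an estimated correlation 0 lists were. A lower share of hepatocyte RNA alone would raise these markers alike. The list medians ran from a log2 difference of 0.55 for cholangiocytes to 1.91 for neutrophils (permutation test with 100000 permutations over 107 genes, p = 0.00071, and 0.00281 with a pseudocount of 0.1). This test treats genes as independent, while the estimated correlation within a list ran from 0.011 for dendritic cells to 0.797 for endothelial genes. Its p does not measure the spread between libraries, so it cannot decide on the share of hepatocyte RNA. Residual blood would scale the excess of neutrophil and monocyte genes with haemoglobin. Between injured KO replicates 1 and 2 the log2 ratio of haemoglobin was 2.91, and that of the excess in 30 neutrophil and monocyte genes had a median of 0.04 (interquartile range -0.60 to 0.46). For the immune lists it stays open, as a hypothesis, whether these livers held more immune cells or more active ones. Values from whole tissue cannot part these. Neither would cover the endothelial and stellate lists (medians of 1.27 and 0.96), and a lower share of hepatocyte RNA stays open too. Lists of hepatocyte genes had medians of 0.092 (secretory), -0.003 (pericentral) and 0.303 (periportal) between injured KO and injured floxed livers. None of them was called (camera adjusted p = 0.776, 0.966 and 0.776). After injury the Kupffer cell median was -1.91 in floxed and 0.97 in KO livers, the endothelial -0.93 and 0.51, and the neutrophil 1.29 and 3.28. The difference thus holds falls in floxed livers as well as rises in KO livers.

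Injured KO replicate 1 listed more genes above 0 than the other libraries (32782, against 27058 for its partner). Greater depth is argued against, since thinned to 18381670 fragments it still had 30017 genes with whole fragments above 0, against 26173 in the highest of the other libraries unthinned. Genomic DNA in the library would give receptor genes of smell and taste as many fragments per kb as other silent genes. Of 1525 such receptor genes 794 were above 0 in injured KO replicate 1 and 370 in its partner. Between 100 and 245 were in the floxed and H2O-treated libraries. The ratio of the rates in receptor and other silent genes was 0.509 (95% interval 0.469 to 0.552, over 964 and 2658 genes). This lay between the values fixed for and against, so DNA in the first of these libraries, injured KO replicate 1, cannot be told apart from low-level RNA. Without this library 5635 genes differed between injured KO and injured floxed livers.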

How the results depend on the processing

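Chosen only after the values were seen were voom on recovered fragments, the scaling without mitochondrial and haemoglobin genes, and the filter of at least 5 FPKM in 2 libraries. Of 190 gene results named in the text, 165 kept their side of the threshold and were not reversed under each of the 20 alternatives that gave them a value. A reversal is a change of sign in a gene that passed in the main fit or in the alternative. Changes of sign in genes that passed in neither were not counted. Over 3696 values, 43 lost a call, 33 gained one and 3 reversed. The 3 were those of Alb after quantile normalisation, at 0.48 for injury averaged over both genotypes, 0.65 for injury in floxed livers and -0.65 for KO against floxed under injury. The cause was not tested.

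A filter at a mean of 5 FPKM tests fewer genes, and the counts dropped to 3952 (average injury effect), 3686 (floxed), 3519 (KO), 3397 (KO against floxed under injury) and 2440 (interaction). With at least 5 FPKM in 2 libraries they were 5170, 4723, 4658, 4304 and 3139 in the same order. For KO against floxed under H2O, where 1 gene passed, a pseudocount of 0.1 gave 6 genes, no filter 16, a mean of 5 FPKM 17, voom 14, at least 5 FPKM in 2 libraries 13, a model of only the groups compared 0 (906 at an unadjusted p under 0.05) and the replicate block 0. The cause was not tested.

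Leaving out 1 library at a time gave between 8459 and 9217 genes for the average injury effect, 5559 and 8126 in floxed livers, 7264 and 8303 in KO livers, 5013 and 7303 for KO against floxed under injury, 0 and 1 under H2O, and 2997 and 5019 for the interaction. The lowest interaction count came without injured floxed replicate 1. With the replicate block the counts were 9386, 7711, 8533, 7037, 0 and 4616. Between groups the deviations of libraries with the same number correlated by 0.27 between the H2O-treated groups and by -0.10 to 0.03 between the other 5 pairs of groups.

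Among gene lists, camera with an estimated correlation called 0 in each of the 6 comparisons, against 19, 16, 20, 19, 12 and 18 with the preset correlation. Fry, which does not compare a list with other genes, called 33 for the average injury effect, 29 in floxed and 27 in KO livers. It called 22 for KO against floxed under injury, 0 for KO against floxed under H2O and 23 for the interaction. With an estimated correlation camera also uses the 4 residual degrees of freedom of the model. The estimate was under the preset value for the p53 (0.003) and lipid synthesis (-0.016) lists, which lost their calls as well. For these lists a higher correlation cannot account for the loss. For the others the effects of correlation and degrees of freedom were not tested apart.

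Depth limits what can be seen of low genes: in the shallowest library 1 fragment in a gene of 1 kb is 0.0544 FPKM.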

Other observations

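The test of the lower mean of Lyz2 against other macrophage markers was chosen only after the result was seen. Glutamine and glutamate genes are of interest beside Glul, since glutamine synthetase makes glutamine from glutamate and ammonia. Of 21 such genes 10 rose and 8 fell on average after injury (camera adjusted p = 0.124; estimated correlation, adjusted p = 0.356), among them the amino acid transporter Slc38a2 (2.06 ± 0.17), asparagine synthetase Asns (2.26 ± 0.27) and the liver glutaminase Gls2 (-2.22 ± 0.16). Between injured KO and injured floxed livers 5 were higher and 5 lower (camera adjusted p = 0.966; estimated correlation, adjusted p = 0.986), with Gfpt1 of hexosamine synthesis at -2.23 ± 0.20, the alanine transaminase Gpt2 at -1.48 ± 0.21 and the glutamine transporter Slc1a5 at 1.08 ± 0.14.

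The lists of fatty acid oxidation and clock genes did not pass either. Of 19 fatty acid oxidation genes 10 fell and 0 rose on average after injury (camera adjusted p = 0.186; estimated correlation, adjusted p = 0.711), with the lipid-sensing receptor Ppara at -1.89 ± 0.12. Between injured KO and injured floxed livers 5 were higher and 3 lower (camera adjusted p = 0.776; estimated correlation, adjusted p = 0.986), with a median of 0.28 that was -0.02 after quantile normalisation. The lower ones include Cpt1a, which lets fatty acids into mitochondria (-1.88 ± 0.15). Of 16 clock genes 7 rose and 7 fell on average after injury, with a median of -0.21 (0.04 after median centring) and a mean of 0.07 (camera adjusted p = 0.691; estimated correlation, adjusted p = 0.837). Among them were Per1 (2.84 ± 0.16), Nr1d1 (2.33 ± 0.12) and Arntl (-2.01 ± 0.10). Between injured KO and injured floxed livers 3 were higher and 6 lower (camera adjusted p = 0.831; estimated correlation, adjusted p = 0.986), with Nr1d1 at 3.31 ± 0.17 and Tef at -1.72 ± 0.28. The hour of collection is not given in the sources used here.

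Lyz2 had a lower mean in H2O-treated KO than in H2O-treated floxed livers (-2.61 ± 0.40, adjusted p = 0.16), a difference that passed with voom (-2.79, adjusted p = 0.0232). A smaller number of macrophages would lower the other macrophage markers as much. The 27 others had a median of -0.67 (interquartile range -0.94 to -0.20), 0 of them were as low, and Lyz2 lay below their median by -1.94. With a pseudocount of 0.1 Lyz2 was at -2.75 and the others at a median of -0.93 (-1.40 to -0.73). The 11 markers with a mean of at least 5 FPKM in H2O-treated floxed livers had a median of -0.91 (-1.34 to -0.82). Lyz2 thus lay lower than these markers as a set. The markers are not independent, with an estimated correlation of 0.351 within the Kupffer cell list and 0.326 within the monocyte list. Their spread does not measure that between libraries, and the Lyz2 difference itself did not pass. The comparison therefore cannot decide on an even loss of macrophages. An earlier test against the lowest marker alone, Marco (-1.80), had not decided either, with a difference of -0.81 and an SE of 0.60. Fewer cells of a kind rich in Lyz2 stay open, as does a loss of Lyz2 transcript from the Cre allele. The latter may be at work because the Cre is carried by the Lyz2 locus, and it remains a hypothesis, as Lyz2 was at 36.3 FPKM in injured KO livers, above the 20.2 FPKM of injured floxed livers.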
